A study of Mus musculus with 6 samples.

How the data were processed

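RNA of CT26 cells was sequenced in 6 libraries, 3 treated with DMSO, the solvent, and 3 with 10 µM irinotecan for 24 h, grouped by the titles and treatment labels. The series design speaks of duplicates, while the labels give 3 libraries per group, and all 6 were used. The labels name total RNA extracted with Trizol and checked for integrity, and standard Illumina libraries; the selection of RNA and the strandedness are not given in the sources used here, so antisense and overlapping genes are uncertain. Per the submitters' processing notes, fastp 0.19.3, HISAT2 2.1.0, featureCounts 1.6.2, StringTie 1.3.4d, DESeq2 1.22.1, edgeR 3.24.3 and the genome build GRCm39 were used, with no role given for each.

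The deposited table, per the file headers, holds a count and an FPKM value per gene and library. The counts are whole numbers, unnormalized, deposited by the authors for 11604 genes (10832 protein-coding, 628 lncRNA, 144 TEC, a class of transcripts not yet backed by experiment), 13 of them mitochondrial. The FPKM values deposited by the authors divide these counts by gene length and library size; they were used only to recover relative gene lengths. The authors' deposited table also gives a log2 fold change, a p-value and an adjusted p-value per gene. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment over exactly these genes, with a largest difference of 1.7e-15. No count in the table was 0 and the lowest sum over the 6 libraries was 58, so genes with few counts had been left out before deposit, and markers of absent cell types cannot be measured at 0. The deposited log2 fold changes correlated at -1.0 across genes with log2 irinotecan over DMSO from the counts, so every direction was taken from the counts. Coordinates are those of the table, on GRCm39. The reference annotation at hand, GENCODE M21, is on GRCm38: 11584 gene IDs were shared and 251 of them had the same start and end, so no coordinate was taken from it. The GO text of 1243 genes was not used.

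The total count per library was 16052326 to 17294496. Depth sets the precision together with the spread between libraries and the 3 libraries per group. Data with the means, spread and depth of these libraries were simulated over 11556 genes for the comparison of irinotecan with DMSO. In them 54.2% of genes changed 1.25-fold, 91.4% of genes changed 1.5-fold and 95.7% of genes changed 2-fold were recovered. In the same simulation 10 of 172 calls (5.81%) were unchanged genes, and 1 gene was called with none changed. The simulation changed 59, 70 and 69 genes by these folds, against 2559 genes called in the data. Its Benjamini-Hochberg cutoff was therefore stricter, and its recovery may be understated. Replicates within a group differed by more than sampling noise (chi-square per degree of freedom 4.24 to 6.47), so no library was treated as a second deposit of another; this does not show that they came from separate cultures.

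Counts were tested in R 4.3.3 with edgeR 4.0.16: the default filterByExpr, which kept 11599 genes (5 did not pass), TMM normalization, robust glmQLFit and glmQLFTest of irinotecan against DMSO, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The biological coefficient of variation was 5.57%. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. CPM values are TMM-normalized over the listed genes, and log2 CPM uses a prior count of 2. Gene lists, 23 in all, were fixed before the data were examined and tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry; p-values were adjusted over the 23 lists. The lists were p53 targets, G1/S and DNA replication, G2/M and mitosis, homologous recombination and Fanconi, replication-dependent histones, interferon-stimulated genes, MHC class I antigen presentation, cytosolic nucleic acid sensing, chemokines and cytokines, NF-kB targets, checkpoint and NK ligands, damage-associated and heat shock genes, unfolded protein and integrated stress response, cell death machinery, irinotecan targets with metabolism and transport, NRF2 targets and ferroptosis, immediate early genes, senescence secretome and cell cycle inhibitors, cholesterol synthesis, ribosome biogenesis, extracellular matrix and EMT, haematopoietic markers, and endothelial and epithelial markers. Gene span was start to end in the table, compared in bins of 10, 30, 100 and 300 kb with an exact permutation of the 6 libraries.

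Genes named in the text follow a rule fixed before the data were examined: Top1, Trp53, Cdkn1a, Cd274, B2m, H2-K1, Cgas, Sting1, Ifnb1, Cxcl10, Ccl5 and Calr whatever their result; the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap, with a mean of at least 5 CPM in the higher group and a symbol that is not a clone or model number; and of each list up to 2 higher and 2 lower members with the smallest p, or, in a list with none past the threshold, up to 2 with the smallest p. Markers of other cell types at 1 CPM or more could be named as well. A gene that the rule names is not reported here.

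The alternatives were DESeq2 1.42.0 size factors in edgeR, total counts as the only scaling, no filter, at least 1 CPM in 3 libraries, DESeq2's Wald test, limma-voom, the replicate number as a block, leaving out each library in turn, a test against 1.5-fold (glmTreat), and for lists the estimated correlation and fry. For the closing section, pseudogenes of every type in GENCODE M21, processed or not, were aligned to protein-coding transcripts with minimap2 2.31. Of 13523 pseudogenes, 6545 had a match at 90% identity over 50% of their length. GO terms of 15 to 300 tested genes were tested with a one-sided hypergeometric test. The tests were tried first on simulated data with known answers.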

Results

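CT26 is a colon carcinoma cell line from the BALB/c mouse that is widely used as a transplantable tumor in studies of anti-tumor immunity. Irinotecan (CPT-11) is a prodrug that carboxylesterases turn into SN-38, an inhibitor of DNA topoisomerase I. RNA was measured in 3 DMSO libraries and in 3 libraries from cells exposed to 10 µM irinotecan for 24 h. The libraries held 16052326, 16649571 and 16482287 counts in DMSO and 17223297, 17049072 and 17294496 with irinotecan, over 11604 listed genes. Mitochondrial genes took 1.885% to 2.23% of the counts per library. The labels do not say whether the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The comparison asked which transcripts irinotecan changed in the tumor cells, with the genes of immune recognition in view, as the title of the series puts it.

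With irinotecan, 32 of 32 interferon-stimulated genes, 18 of 27 p53 targets and 15 of 20 genes of MHC class I antigen presentation were higher, and 13 of 22 immediate early genes and 13 of 22 ribosome biogenesis genes were lower. As lists they passed the camera test with a preset correlation and not with an estimated one. There the adjusted p was 0.19 for each except immediate early genes, at 0.24. With an estimated correlation camera takes its degrees of freedom from the 6 libraries, so few lists could pass, and 0 of the 23 did. Of 11599 genes tested, 2559 (22.1%) changed, 1369 higher and 1190 lower. The changes were small. The median absolute log2 fold change was 0.37 among the genes that rose and 0.24 among those that fell, and 132 genes changed at least 2-fold, 121 of them higher and 11 lower. Against a threshold of 1.5-fold in place of no change, 55 genes passed, 54 higher and 1 lower. The 3 irinotecan libraries did not overlap the 3 DMSO libraries in 4305 genes (37.1%), where chance gives 10%. Correlations of log2 CPM across genes were 0.9933 to 0.9946 within groups and 0.9867 to 0.9911 between groups, and genes are not independent replicates. With total counts as the only scaling, 66.1% of the calls were higher, against 53.5% here. Without irinotecan replicate 1 the count of changed genes was 1393 (804 higher, 589 lower, 82 at least 2-fold), and without DMSO replicate 2 it was 1709, with 726 lower.

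**Figure D1:**
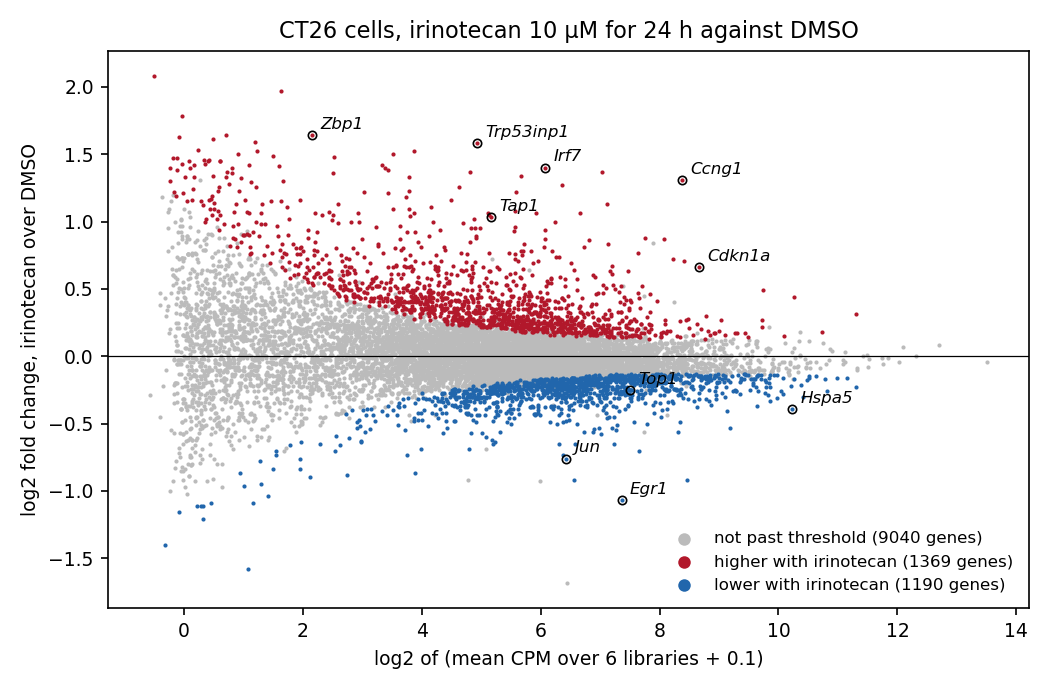
Each point is 1 of the 11599 genes tested, with the log2 of mean CPM over the 6 libraries on the x axis and the log2 fold change of irinotecan over DMSO on the y axis. Genes past the threshold are red where higher (1369) and blue where lower (1190), and 10 named genes are circled.

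The largest rises among genes chosen by a rule fixed before the data were examined included sensors and effectors of the interferon response. Zbp1 (ENSMUSG00000027514, chromosome 2, 173048405 to 173060716, GRCm39), a sensor of Z-form nucleic acids, rose from 2.1 ± 0.656 to 6.56 ± 0.508 CPM (SD, n = 3), a log2 fold change of 1.64 ± 0.21 (SE). Irf7 (chromosome 7, 140842619 to 140846394), a transcription factor of the type I interferon response, rose from 37 ± 1.51 to 97.8 ± 13.3 CPM. Cmpk2 rose by 1.42 ± 0.16 and Gbp2, an interferon-induced GTPase, by 1.48 ± 0.18 on the log2 scale. Trp53inp1, a p53 target, rose from 15.1 ± 2.54 to 45.3 ± 3.82 CPM, and Inka2, Anxa8 and the small heat shock protein gene Cryab rose by 1.52, 1.5 and 1.4 on the log2 scale. The largest falls by the same rule were those of Egr1 (chromosome 18, 34992876 to 34998037), a growth factor-induced transcription factor, from 223 ± 7.88 to 106 ± 4.97 CPM (log2 fold change -1.07 ± 0.051, adjusted p = 3.3e-12), and of Egr3 (-0.87), Jun (-0.76), Flrt3 (-0.90) and Sh2d6 (-0.88). The other falls held less well. Grem1, an antagonist of bone morphogenetic proteins, fell by 0.92 (adjusted p = 0.011), and the call was lost without DMSO replicate 2 or 3 (adjusted p = 0.066 and 0.07, the highest of 13 alternatives). Ppp1r15a, a phosphatase subunit of the stress response, fell by 0.92 (adjusted p = 0.046), and the call was lost without any 1 library except irinotecan replicate 1, with an adjusted p from 1.3e-05 to 0.13 over 13 alternatives. Avil fell by 0.73 (adjusted p = 0.03), a call lost with DESeq2 (0.052) and without DMSO replicate 2, DMSO replicate 3 or irinotecan replicate 2, with an adjusted p of 5.6e-07 to 0.12 over 13 alternatives.

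All 32 interferon-stimulated genes measured, of 34 fixed beforehand, rose with irinotecan, at a median log2 fold change of 0.98 (1.97-fold) and a range from 0.26 to 1.64. Usp18, the protease that removes ISG15 and restrains interferon signalling, rose from 28.6 ± 1.46 to 66.9 ± 5.87 CPM (SD, n = 3, adjusted p = 2.5e-10), and Irf7 by 1.40 ± 0.082 (SE, adjusted p = 7.8e-10). The mean of the list lay 1.08, 0.84 and 0.99 above the DMSO mean in irinotecan replicates 1 to 3, on the log2 scale, and between -0.08 and 0.07 in the DMSO libraries. All 32 passed when adjusted over the list alone. The list as a whole stood above other genes with a preset correlation (camera, adjusted p = 1.2e-25), and adjusted p = 0.19 with an estimated correlation. Members of near-identical families, such as the Oas1 genes and Ifit3 with Ifit3b, can share reads and are uncertain as single genes. Markers of other cell types were nearly absent from the table. Of 21 haematopoietic markers, 1 was listed, Cd68, which rose from 2.36 ± 0.612 to 4.01 ± 0.265 CPM (adjusted p = 0.018, lost without DMSO replicate 1 or 3 or irinotecan replicate 1 or 3, at most 0.07 over 13 alternatives). Of 16 endothelial and epithelial markers, 3 were listed; Cdh17, an intestinal cadherin, rose from 0.9 ± 0.41 to 2.4 ± 0.443 CPM, and Krt18 fell by 0.23 (adjusted p = 0.025, lost without DMSO replicate 2, irinotecan replicate 1 or irinotecan replicate 3, at most 0.14 over 13 alternatives). Both lists missed the threshold as a whole (camera, adjusted p = 0.18 and 0.87). CT26 is itself a colon carcinoma line, so the epithelial genes Cdh17 and Krt18 may be its own and do not mark other cells.

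Of 20 genes of MHC class I antigen presentation measured, of 23 fixed, 15 rose and 5 did not pass. Tap1 (chromosome 17, 34406527 to 34416199), a subunit of the peptide transporter, rose from 23.5 ± 2.1 to 47.8 ± 4.37 CPM (SD, n = 3), a log2 fold change of 1.03 ± 0.086 (SE, adjusted p = 2.3e-08). Tapbp, tapasin, rose by 0.81 ± 0.066, and B2m, the invariant light chain, by 0.30 ± 0.045 (395 ± 8.07 to 486 ± 11.6 CPM). The heavy chain gene H2-K1 rose by 0.16 ± 0.054 (adjusted p = 0.042), but the call was lost with DESeq2 (0.067) and without DMSO replicate 2 or 3 or irinotecan replicate 1, 2 or 3 (0.051 to 0.24), with an adjusted p of 0.0017 to 0.24 over 13 alternatives. MHC genes are among the most polymorphic between mouse strains, and BALB/c reads counted on a C57BL/6 reference, as GRCm39 is, can be lost or misplaced. The list gave an adjusted p = 2.3e-08 with the preset correlation and adjusted p = 0.19 with an estimated correlation, and 15 rose when adjusted over the list alone.

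The fixed list of cytosolic nucleic acid sensing did not move as a group. Of 14 measured, of 18 fixed, 3 rose and 1 fell, with a median log2 fold change of -0.02 and a mean of 0.09 (camera, adjusted p = 0.81, direction higher). Samhd1, a nucleotide triphosphohydrolase, rose by 0.51 ± 0.05 (SE) and Tlr3, the endosomal receptor of double-stranded RNA, by 0.80 ± 0.12. Sting1, the adaptor of the cGAS pathway, rose by 0.28 ± 0.069 (adjusted p = 0.0057), while Cgas stood at 38.4 ± 3.09 and 38.5 ± 2.54 CPM (SD, n = 3, adjusted p = 0.97). Myd88 fell by 0.25 (adjusted p = 0.014), a call lost without DMSO replicate 2 (0.057, the highest of 13 alternatives). Adjusted over the list alone, 4 rose and 2 fell. The list does not hold every sensor. Others, such as Zbp1 (log2 fold change 1.64), were fixed in the interferon list, where all 32 measured genes rose. Ifnb1, which encodes interferon beta, has no row in the table analysed here.

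Of 10 chemokines and cytokines measured, of 28 fixed, 3 rose and 2 fell. Cxcl10, a chemokine that attracts T cells, rose from 12.2 ± 0.551 to 17.1 ± 0.634 CPM (SD, n = 3, adjusted p = 0.0013), Lif by 0.42 ± 0.076 (SE), and Il15 by 1.5 ± 0.29 from a level of 0.927 CPM. Vegfa, the vascular growth factor, fell by 0.25 ± 0.051. Csf1, the macrophage growth factor, fell by 0.17 (adjusted p = 0.024), a call lost with total counts as the only scaling and without DMSO replicate 2, irinotecan replicate 1 or irinotecan replicate 2 (2.2e-04 to 0.18 over 13 alternatives). Ccl5 had a log2 fold change of 0.42 ± 0.24 at 2.34 and 3.13 CPM (adjusted p = 0.22). Adjusted over the list alone, 3 rose and 2 fell, and the list missed the threshold (camera, adjusted p = 0.13). Checkpoint and natural killer cell ligands gave 5 higher and 2 lower of 12 measured, of 24 fixed, with 6 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.13, and 0.032 without irinotecan replicate 1, the lowest of its 11 alternatives, which reached 0.56). Lgals9, galectin-9, rose by 0.57 ± 0.057 and Tnfsf9, the ligand of the T-cell costimulator 4-1BB, by 0.92 ± 0.13, while Pvr, the poliovirus receptor homolog bound by TIGIT, fell by 0.34 ± 0.052. Nectin2 fell by 0.23 (adjusted p = 0.033), a call lost with total counts alone and without DMSO replicate 2, irinotecan replicate 1 or irinotecan replicate 2 (0.0017 to 0.21 over 13 alternatives). Cd274, which encodes PD-L1, had a log2 fold change of 0.44 ± 0.21 at 4.31 ± 1.01 and 5.86 ± 1.81 CPM (adjusted p = 0.15), and passed without DMSO replicate 3 (0.047, the lowest of 13 alternatives, which reached 0.63). NF-kB targets gave 4 lower and 12 not past the threshold of 16 measured, of 18 fixed, at a median of 0.02 and a mean of 0.03 although camera gave the direction as lower (adjusted p = 0.87). Ier3 fell by 0.50 ± 0.063, and Tnfaip2 by 0.18 (adjusted p = 0.015), a call lost without DMSO replicate 2 or irinotecan replicate 1 (0.083 and 0.11, the highest of 13 alternatives). The number of NF-kB targets lower was 1 without DMSO replicate 2 and 2 without irinotecan replicate 1, 2 or 3, and adjusted over the list alone 1 was higher and 4 lower.

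Among p53 targets, 18 rose, 1 fell and 8 did not pass, of 27 measured and 30 fixed, with a median log2 fold change of 0.52 (1.44-fold). Ccng1 (ENSMUSG00000020326, chromosome 11, 40639379 to 40646138), cyclin G1, rose from 192 ± 3.62 to 474 ± 14.6 CPM (SD, n = 3, adjusted p = 2.1e-14), the smallest p of the list. Ephx1, the microsomal epoxide hydrolase, rose from 72.9 ± 3.58 to 188 ± 0.823 CPM, and Cdkn1a (chromosome 17, 29309950 to 29319701), the p21 inhibitor of cyclin-dependent kinases, from 314 ± 32.6 to 497 ± 27.4 CPM (log2 fold change 0.66 ± 0.063, SE). Trp53 itself stood at 238 ± 5.97 and 226 ± 1.82 CPM (adjusted p = 0.28). Plk3, a polo-like kinase, fell by 0.65 ± 0.12 (adjusted p = 0.0075), a call lost without DMSO replicate 3 (0.07, the highest of 13 alternatives). The list gave an adjusted p = 9.2e-11 with the preset correlation and adjusted p = 0.19 with an estimated correlation, and 21 rose and 2 fell when adjusted over the list alone.

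**Figure D2:**
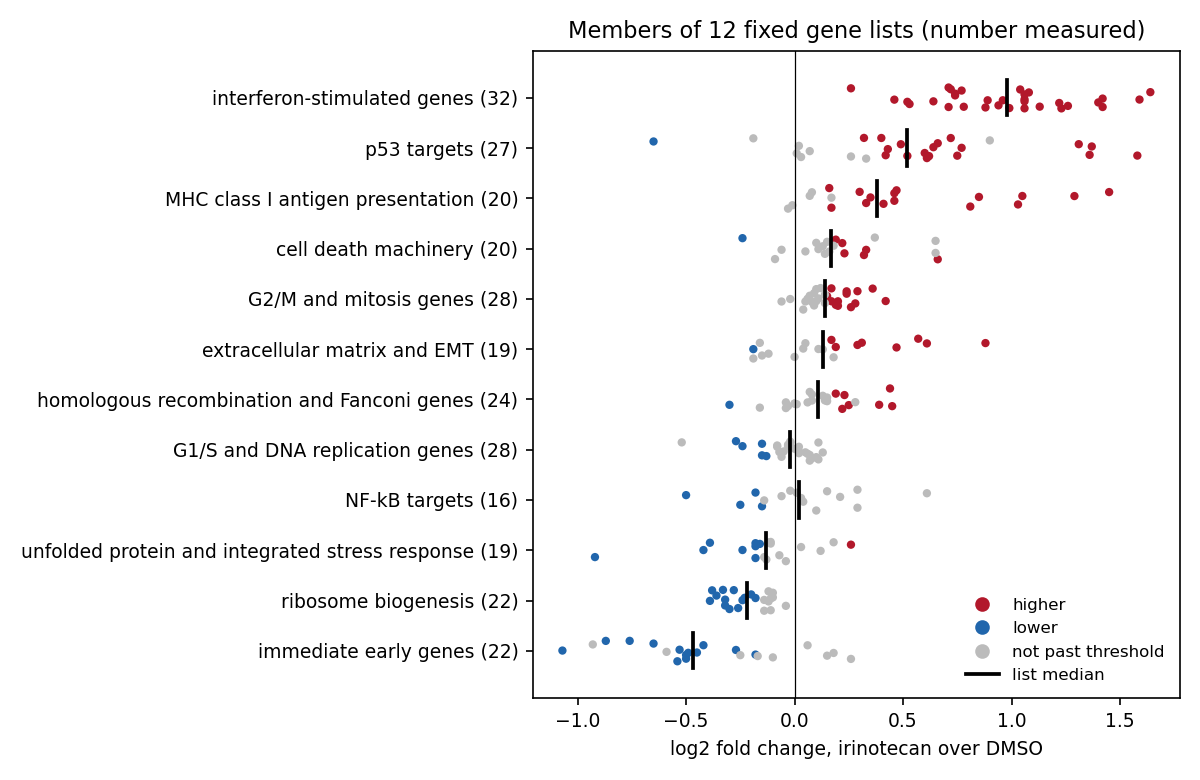
Each point is 1 member of 12 of the 23 gene lists, with its log2 fold change of irinotecan over DMSO on the x axis; the number measured stands beside each list name. Red and blue points passed the threshold as higher and lower, grey points did not, and black bars give list medians, from 0.98 for interferon-stimulated genes to -0.47 for immediate early genes.

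Of 28 genes of G2 and mitosis measured, 13 rose by small amounts and 15 did not pass, with a median log2 fold change of 0.14. Cdc20, an activator of the anaphase-promoting complex, rose from 156 ± 8.73 to 209 ± 18.7 CPM (SD, n = 3), and Kif20a, a mitotic kinesin, by 0.36 ± 0.046 (SE). The list gave an adjusted p = 9.4e-06 with the preset correlation and adjusted p = 0.14 with an estimated correlation. Adjusted over the list alone 16 rose, and without irinotecan replicate 1 the number over all genes was 8. Of 28 G1/S and DNA replication genes, 5 fell and 23 did not pass (median -0.02, camera adjusted p = 0.31, 5 lower adjusted over the list alone). Mcm2, a subunit of the replicative helicase, fell by 0.27 ± 0.053 and Pola1, the catalytic subunit of DNA polymerase alpha, by 0.24 ± 0.05. The number lower was 2 without DMSO replicate 1, irinotecan replicate 1 or irinotecan replicate 3, 3 without DMSO replicate 2, and 2 with total counts as the only scaling. Among 24 homologous recombination and Fanconi genes, 7 rose and 1 fell, both over all genes and adjusted over the list alone. Rad54l rose by 0.45 ± 0.09 and Exo1 by 0.44 ± 0.096, and H2ax fell by 0.30 (adjusted p = 0.0094, lost without DMSO replicate 2 at 0.06, the highest of 13 alternatives). That list passed narrowly (camera, adjusted p = 0.043), with adjusted p = 0.56 with an estimated correlation, and lost its call without DMSO replicate 1 or 2 or irinotecan replicate 1 or 2 (0.055 to 0.23); 3 genes rose without DMSO replicate 2 or without irinotecan replicate 1. Of 24 replication-dependent histone genes, 4 were listed, and edgeR, DESeq2 and limma-voom each called 0 of them, with 1 at an unadjusted p under 0.05. Their median was -0.06 and their mean 0.16 (camera, adjusted p = 0.87), and H1f4 and H1f2 had log2 fold changes of 0.87 ± 0.39 and -0.12 ± 0.14. Histone genes are near-identical copies and uncertain one by one.

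Of 22 immediate early genes measured, 13 fell and 9 did not pass, with a median log2 fold change of -0.47. Jun fell from 109 ± 12.3 to 64.2 ± 3.22 CPM (SD, n = 3, adjusted p = 9.4e-08), beside Egr1. The list gave an adjusted p = 6.3e-08 with the preset correlation and adjusted p = 0.24 with an estimated correlation, and 1 rose and 16 fell when adjusted over the list alone. All 22 genes of ribosome biogenesis had a negative log2 fold change, of which 13 passed, with a median of -0.22. Nop56, a protein of box C/D small nucleolar ribonucleoproteins, fell from 507 ± 19.7 to 405 ± 13.3 CPM and Wdr43 from 318 ± 15.6 to 243 ± 19.1 CPM. The list gave an adjusted p = 1.9e-08 with the preset correlation and adjusted p = 0.19 with an estimated correlation, and 18 fell when adjusted over the list alone. Of 19 genes of the unfolded protein and integrated stress response measured, of 20 fixed, 8 fell, 1 rose and 10 did not pass (median -0.13, adjusted p = 0.0028, and adjusted p = 0.24 with an estimated correlation). Hspa5, the chaperone BiP, fell from 1358 ± 75.9 to 1040.2 ± 33.1 CPM and Ddit3, the transcription factor CHOP, by 0.42 ± 0.067 (SE), while Ddit4, an inhibitor of mTORC1, rose by 0.26 ± 0.066. Adjusted over the list alone the counts were 1 higher and 8 lower, and 5 fell without DMSO replicate 2, irinotecan replicate 1 or irinotecan replicate 3.

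Cell death genes and damage-associated genes changed in part. Of 20 cell death genes measured, of 25 fixed, 6 rose, 1 fell and 13 did not pass (median 0.17, adjusted p = 0.0019, and adjusted p = 0.19 with an estimated correlation; 10 higher and 1 lower adjusted over the list alone). The members named by the rule inhibit apoptosis: Bcl2l1 and Xiap rose by 0.23 ± 0.054 and 0.22 ± 0.056 (SE), and Mcl1 fell by 0.24 ± 0.052. The other 4 members past the threshold, chosen after their values were seen, promote cell death: Bcl2l11 rose by 0.33, Gsdmd by 0.32, Bid by 0.19 and Bnip3 by 0.66. Over the 6 leave-one-out fits Bcl2l11 stayed past the threshold, Gsdmd lost the call without DMSO replicate 2 (adjusted p = 0.055), Bnip3 without DMSO replicate 2, DMSO replicate 3 or irinotecan replicate 3 (0.092, 0.19 and 0.17), and Bid in each (up to 0.13). With total counts as the only scaling, 10 cell death genes rose. The list does not hold every gene that promotes cell death. Bax (0.42), Bbc3 (0.4), Apaf1 (0.61), Pidd1 (0.64) and Tnfrsf10b (0.43) were fixed among the p53 targets and rose on the log2 scale. They were chosen after their values were seen, from a list in which 18 genes rose, 1 fell and 8 did not pass. Of 11 damage-associated and heat shock genes measured, of 16 fixed, 3 rose and 2 fell (median 0.08, camera adjusted p = 0.3; 4 higher and 2 lower adjusted over the list alone). Anxa1 rose by 0.19 ± 0.047, and Hspa8 by 0.49 ± 0.089 (adjusted p = 0.0044, lost without DMSO replicate 3 at 0.088, the highest of 13 alternatives). The falls of Hspd1 and Hspe1, which encode the mitochondrial chaperonins, were -0.15 each and did not pass with total counts as the only scaling (adjusted p = 0.06 and 0.08), nor without DMSO replicate 1, irinotecan replicate 1 or irinotecan replicate 3, with ranges that reached 0.11 and 0.17 over 13 alternatives. Hspe1 lost its call also without DMSO replicate 2 or irinotecan replicate 2. Calr, whose protein calreticulin is a surface signal of dying cells, stood at 578 ± 24 and 568 ± 27.1 CPM (SD, n = 3, adjusted p = 0.76).

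The drug's own target fell slightly. Top1 (ENSMUSG00000070544, chromosome 2, 160487808 to 160564684), topoisomerase I, fell from 197 ± 7.46 to 165 ± 12.3 CPM (SD, n = 3), a log2 fold change of -0.25 ± 0.055 (SE, adjusted p = 0.0023). Of 17 genes of irinotecan targets, metabolism and transport measured, of 29 fixed, 3 rose, 4 fell and 10 did not pass, with no shift of the list (camera, adjusted p = 0.87; 6 higher and 5 lower adjusted over the list alone). Ces2g, a carboxylesterase, rose by 1.07 ± 0.2 on the log2 scale, and reads of this family can be shared between its near-identical members. Abcc4, an efflux transporter, fell by 0.34 ± 0.057. Top2a, the type II enzyme, rose by 0.17 (adjusted p = 0.01), a call lost without DMSO replicate 1 or irinotecan replicate 2 (0.064 and 0.054, the highest of 13 alternatives). The list counts were 1 higher and 2 lower without irinotecan replicate 2.

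Extracellular matrix and EMT genes gave 8 higher and 1 lower of 19 measured, of 24 fixed (median 0.13, adjusted p = 0.025, and adjusted p = 0.19 with an estimated correlation; 11 higher and 5 lower adjusted over the list alone). Col1a1 and Col3a1, which encode fibrillar collagens, rose by 0.47 ± 0.046 and 0.57 ± 0.057 (SE) on the log2 scale. The lower gene, Zeb2, a transcriptional repressor, fell by 0.19 (adjusted p = 0.041) and was past the threshold in 6 of 13 alternatives, with an adjusted p of 0.0011 to 0.24; it lost the call with DESeq2, limma-voom and total counts alone, and without DMSO replicate 2 or 3 or irinotecan replicate 1 or 2. Of 18 cholesterol synthesis genes measured, of 20 fixed, 5 rose and 1 fell (median 0.15, adjusted p = 0.043, and adjusted p = 0.74 with an estimated correlation; 7 higher and 1 lower adjusted over the list alone). Insig1, which retains the sterol sensor in the endoplasmic reticulum, rose by 0.53 ± 0.055 (SE), and Idi1 by 0.25 (adjusted p = 0.01), a call lost without DMSO replicate 2 or irinotecan replicate 1 (0.07 and 0.065, the highest of 13 alternatives). The cholesterol list missed the threshold without DMSO replicate 2, DMSO replicate 3 or irinotecan replicate 1 (0.16, 0.1 and 0.2), each of which left 2 genes higher, while 9 were higher without DMSO replicate 1. The senescence secretome and cell cycle inhibitors gave 5 higher and 3 lower of 12 measured, of 21 fixed, with the same counts adjusted over the list alone, a median of 0.05 and a mean of -0.01 (camera, adjusted p = 0.81). Glb1 and Mmp13 rose by 0.27 ± 0.068 and 0.51 ± 0.13, and Plaur, the urokinase receptor, and Timp1, an inhibitor of metalloproteinases, fell by 0.65 ± 0.056 and 0.36 ± 0.057. The number higher was 2 without irinotecan replicate 1 and 3 without DMSO replicate 3 or irinotecan replicate 3. Of 18 NRF2 targets and ferroptosis genes, 2 fell, Fth1 by 0.16 and G6pdx by 0.15 (adjusted p = 0.022 and 0.037), and 16 did not pass (median -0.02, camera adjusted p = 0.59). Both calls were lost without DMSO replicate 1, irinotecan replicate 2 or irinotecan replicate 3, that of Fth1 also without DMSO replicate 2, and that of G6pdx also without DMSO replicate 3 and with total counts as the only scaling. Adjusted over the list alone edgeR called 0 of the 18, of which 4 had an unadjusted p under 0.05. DESeq2 and limma-voom each called 2 over all genes.

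Across the 23 lists, camera with the preset correlation of 0.01 placed 11 past the threshold, 8 higher and 3 lower. With a correlation estimated from each list, 0 were past it. The estimate was 0 for G2/M and mitosis and -0.02 for cell death and for extracellular matrix, all below the preset. Correlation between genes therefore does not account for the loss of these lists. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes, so few lists could pass. Fry, which asks only whether a list moves one way on balance, placed 11 past the threshold. The haematopoietic list, with 1 gene measured, was among them.

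Gene span was compared because topoisomerase I inhibitors slow transcription of long genes. The median log2 fold change was -0.016 for 3048 genes spanning under 10 kb, 0.002 for 10 to 30 kb, 0.009 for 30 to 100 kb, 0.015 for 100 to 300 kb, and -0.048 for 216 genes over 300 kb. Of those 216 genes, 29 (13.4%) fell and 13 (6.02%) rose, against 10.4% and 9.51% of genes under 10 kb. The longest minus the shortest bin gave a log2 difference of -0.049 between irinotecan and DMSO, with SDs of 0.057 and 0.078 among the libraries of each group (two-sided exact permutation test, p = 0.4, n = 3 per group; 3 against 3 libraries cannot go below 0.1). The difference was therefore not larger than the spread between libraries.

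**Figure D3:**
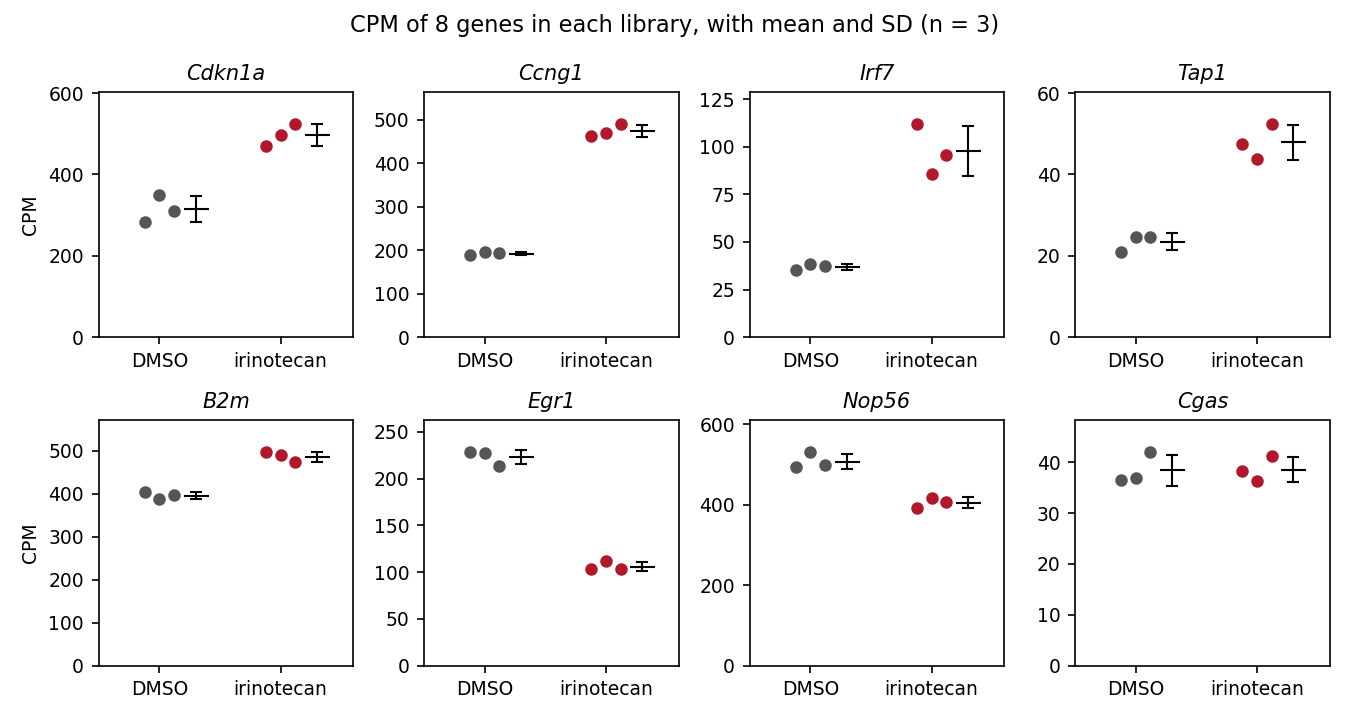
Points give the CPM of each of the 6 libraries for 8 genes, with the y axis from 0 and the mean and SD of n = 3 at the right of each group. Irinotecan libraries lie above DMSO libraries for Cdkn1a, Ccng1, Irf7, Tap1 and B2m, below them for Egr1 and Nop56, and overlap them for Cgas.

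The authors' deposited table gave 2232 genes with an adjusted p under 0.05, of which 2230 were tested here. Its log2 fold changes run from irinotecan to DMSO, the reverse of those given here. Ccng1, for example, has a log2 fold change of -1.30 in the authors' deposited table although its counts rose with irinotecan, and 0 of the 2232 genes had the sign of irinotecan over DMSO. The 133 genes marked down in the authors' deposited table are therefore higher with irinotecan, and the 13 marked up are lower. With the sign turned, 2206 genes were called in both, 353 here only and 24 in the authors' deposited table only.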

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

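With the depth, spread and number of these libraries 54.2% of the smallest simulated changes were recovered, so small changes are partly missed. The simulation changed far fewer genes than were called here, so it may overstate the share missed. Of 78 named genes past the threshold, 58 held under each of 13 alternatives, which leave out the test against 1.5-fold. The call was lost in 20 when 1 library was left out and in 8 in another setting. No call changed sign. Leaving out 1 library gave 1393 to 2362 genes changed, 804 to 1211 higher, 589 to 1151 lower and 82 to 131 at least 2-fold, the lowest each time without irinotecan replicate 1 (1393, 804, 589 and 82); 726 were lower without DMSO replicate 2. Fewer samples lower these counts. Against 1.5-fold, 55 genes passed, 54 higher and 1 lower, since that test asks for a larger change. Total counts as the only scaling gave 2466 genes, 66.1% higher, and moved the median gene by 0.03 on the log2 scale.

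The replicate numbers were not taken to pair the libraries: the correlations of same-numbered deviations were 0.12, 0.04 and 0.08, although all 6 libraries correlated best with their own number, a hint from the data and not the design. With the number as a block, 3628 genes changed, 1808 higher and 1820 lower, the homologous recombination list gave an adjusted p of 0.051, the irinotecan target list turned (0.92), and no other list changed its call.

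With an estimated correlation the 11 lists past the threshold gave adjusted p-values of 0.14 (G2/M), 0.19 (p53 targets, interferon-stimulated genes, MHC class I, cell death, ribosome biogenesis, extracellular matrix), 0.24 (unfolded protein response, immediate early genes), 0.56 (homologous recombination) and 0.74 (cholesterol). Fry gave 0.1 for homologous recombination and 0.26 for cholesterol, and passed chemokines (8.3e-04) and haematopoietic markers (0.041). The haematopoietic list held 1 measured gene, Cd68, so its values are those of 1 gene and not of a list. Total counts alone gave 0.052 and 0.056 for homologous recombination and cholesterol. Leaving out 1 library gave an adjusted p of 0.0092 to 0.23 for homologous recombination, 0.006 to 0.2 for cholesterol, 0.032 to 0.33 for checkpoint ligands, 0.026 to 0.24 for haematopoietic markers (0.026 without DMSO replicate 2), and, with the direction reversed in some fits, 0.41 to 0.99 for histones, 0.79 to 0.99 for irinotecan targets and 0.79 to 1 for endothelial and epithelial markers. At 1 CPM in 3 libraries the histone list reversed (0.68). The cause was not tested.

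Genes near no change turned sign: Cgas from -0.05 to 0.07 and Calr from -0.06 to 0.01 over the leave-one-out fits, and Calr to 0 with total counts alone. For gene span, Spearman's rho across genes was 0.047 and the longest minus the shortest of equal-sized bins of gene-model length 0.001, against -0.049 between span bins; a permutation of 3 against 3 libraries cannot go below 0.1. At least 2-fold, 108 genes were shared with the authors' deposited table. The cause was not tested.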

Other observations

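The tests of GO terms, of the interferon-stimulated genes and of irinotecan replicate 1 were chosen after the results were seen, as were the genes named for GO terms; the tests of pseudogenes and of other splits were written before theirs.

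GO terms given in the deposited table were tested beside the fixed lists, over 9619 genes with GO text (1029 terms in 2 directions, one-sided hypergeometric test with Benjamini-Hochberg adjustment, treating genes as independent), and 49 passed among lower genes and 45 among higher genes. Of 35 small-subunit processome genes, which assemble the small ribosomal subunit and include members of the fixed ribosome biogenesis list such as Nop56 and Nop14, 24 fell (adjusted p = 1.8e-13), against a median of 6 and a highest of 15 in 10000 gene sets matched on mean count. Of 87 tRNA processing genes 25 fell (adjusted p = 1.8e-04, matched median 7, highest 20), led by the tRNA methyltransferase gene Trmt61a (log2 fold change -0.56 ± 0.08, SE) and by Ctu1 (-0.49 ± 0.08), Dus2 (-0.46 ± 0.07) and Mettl1 (-0.46 ± 0.08), which encode tRNA-modifying enzymes. Of 228 RNA splicing genes 53 fell (adjusted p = 3.0e-06, matched median 34, highest 55), a count that 6 of the 10000 matched sets reached. Of 42 translation initiation factor genes 15 fell (adjusted p = 8.2e-04, matched median 9, highest 20), a count that 160 matched sets reached.

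Genes that rose included more of the lysosome and the extracellular matrix than matched sets held. Of 242 lysosome genes 52 rose and 18 fell (adjusted p = 6.8e-04, matched median 28, highest 48); Irgm1, an interferon-induced GTPase, rose by 0.93 ± 0.09 (SE). Of 103 genes of collagen-containing extracellular matrix 31 rose and 10 fell (adjusted p = 6.1e-05, matched median 10, highest 22), with Fbn1, fibrillin-1, at 0.69 ± 0.18. Of 28 kinesin complex genes 11 rose (adjusted p = 0.0072, matched median 3, highest 11), a count that 1 matched set reached. Among the 11 were Stard9 (0.46 ± 0.09), Kifc1 (0.39 ± 0.05) and Kif20a (0.36 ± 0.05), which is also in the fixed G2/M list. Of 73 centriolar satellite genes 22 rose (adjusted p = 0.0012, matched median 8, highest 21), with Cep72 at 0.63 ± 0.11. The 22 include Tap1 (1.03 ± 0.09), which is also in the fixed MHC class I list.

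The rise of interferon-stimulated genes was weighed against 3 technical explanations. The choice between TMM and total counts does not account for the rise. The median log2 fold change of the list was 1.01 with total counts as the only scaling. That scaling moved the median gene by only 0.03, so it could not have removed the rise, and an error shared by both scalings was not tested. A single library as the carrier is argued against, since at least 32 of the 32 genes stayed past the threshold and higher in each of the 6 leave-one-out fits. Haematopoietic cells in the irinotecan cultures cannot be told apart from a response of the tumor cells by their markers, because 1 of the 21 was listed, Cd68, at 4.01 CPM. A response of CT26 cells to irinotecan, the difference the design names, stays open too, and no test here decides between them.

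Genes with many annotated pseudogenes, processed (intronless copies of mRNAs in the genome) or of another type, scattered more within groups. The class was tested after Rps27rt, a copy of the ribosomal protein gene Rps27, was seen at counts of 1446, 394 and 318 in the irinotecan libraries, and Gapdh, with 132 pseudogene matches, at 1188, 489 and 446 in DMSO. Rps27rt also differed between groups, with 1796, 2757 and 1912 counts in DMSO, while Rps27 went from 138 to 197 CPM with irinotecan. Neither passed the threshold (edgeR, adjusted p = 0.17 and 0.099). Their summed CPM was 229 to 316 in DMSO and 233 to 249.6 with irinotecan, and the cause was not tested. The median within-group SD of log2 CPM was 0.0811 for 184 genes with at least 5 matches, against 0.0631 in sets matched on mean count (central 95% of sets up to 0.0691), which is consistent with reads shared between gene and pseudogene. Low counts are argued against as the cause, as the median was 0.0757 against 0.0577 among genes with a mean of at least 500 counts, and so are short transcripts, as the 135 of these genes with counterparts of like count and length had a median of 0.089, against 0.0717 in sets matched on both. Of the 184 genes, 20.1% were called, against 23.6% of genes without a match, and no biological explanation was tested.

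Fewer genes were called without irinotecan replicate 1 (1393) than without any other library. Its sequencing depth is argued against, since its total count differed by 0.3% from the mean of the other irinotecan libraries. Over genes called without it, its change had a slope of 1.03 on the mean change of the others (0.99 to 1.07, bootstrap over genes). The slopes of replicates 2 and 3 were 0.801 and 0.827, each over its own genes and on a mean that includes replicate 1. The interval measures spread between genes and not between libraries. A larger response in replicate 1 would give such slopes, but not every list was largest in it. In irinotecan replicates 1 to 3, interferon-stimulated genes lay 1.08, 0.84 and 0.99 above the DMSO mean on the log2 scale, and p53 targets 0.47, 0.52 and 0.59. The 8 Hsp and Dnaj genes of the fixed heat shock list lay 0.15 above the other irinotecan libraries on the log2 scale, beyond the central 95% of matched sets (up to 0.06), but those of DMSO replicate 1 also lay 0.1 above the other DMSO libraries (matched sets up to 0.05), so a stress state particular to that library cannot be told apart from a difference shared by both libraries numbered 1. The slope describes 1 library, and no biological explanation was tested.

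The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split with a count as large for each of 5 results: 2559 genes changed, 1369 higher, 1190 lower, 132 at least 2-fold, and 11 gene lists. A split has no direction of its own, so higher and lower were set against the larger direction of each other split. The other splits called at most 1 gene, changed at least 2-fold, and at most 7 lists. Each of them keeps part of the treatment difference, since each side holds 2 libraries of one treatment and 1 of the other, so these are not values with no effect.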
